A study of Bos taurus with 18 samples.

How the data were processed

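The series holds 18 libraries of poly(A) RNA from Belgian Blue satellite cells, 3 in each of 6 media, made with a stranded mRNA kit and read to 75 bp. The authors deposited a table of counts, whole numbers of reads per gene identifier, for 27607 Ensembl bovine identifiers. Per the submitters' processing notes, STAR 2.7, featureCounts and the bosTau9 assembly were used. Aligner parameters, the annotation release and the strand setting of the counting are not given in the sources used here. Reads shared by overlapping genes or near-identical copies could therefore be split or lost in ways that the counts do not show. Without a stated strand setting, antisense partners cannot be separated with certainty.

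Each column was matched to a sample by its label, and all 18 columns were used. Groups, times and serum levels came from the labels. The labels call the replicates A, B and C biological triplicates and do not say whether the letters mark animals, cultures or days, so p-values measure the spread between these cultures. A chi-square comparison of the counts of replicate pairs gave 1.95 (GM A and B) to 47.7 per degree of freedom, above sampling noise for every pair, and all libraries were counted as separate replicates. The totals of 16162525 to 28589018 counts give a floor of 3 counts over a group of 3 libraries of 0.0351 to 0.0475 CPM, which covers counting error only.

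Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given (minimum count 10, minimum total 15), which left 14637 genes with 100.0% of the counts, and libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 18 libraries, so that the groups share an estimate of the spread, and each comparison was a two-sided contrast with Benjamini-Hochberg adjustment at 0.05. The 10 comparisons, their tests and most alternatives were fixed before the data were examined, and 2 comparisons were added later. CPM values use the TMM-scaled library totals. The test was tried on simulated counts for DMEM against SFDM with 14497 genes tested and 200 changed genes, 50 at each fold. It recovered 10% of those changed 1.25-fold, 66% at 1.5-fold, 78% at 2-fold and 98% at 4-fold, and 3.82% of its calls were false. This was a single draw with noise independent between genes. The real comparison called 6816 of 14637 genes, so these rates may not carry over to it.

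Gene names were to come from a reference table of the ARS-UCD2.0 assembly. Its column of Ensembl identifiers was empty, 0 identifiers matched a symbol, and the files do not pair them. The 30 symbol lists with 639 genes, the markers of other cell types and the named gene panel fixed before the data were examined were for that reason not analysed here, and checks of GC content and gene length were void. In their place, after the data were seen, 2 sets were defined by DM against GM (adjusted p under 0.05 and at least 2-fold), and switched genes were defined by mean levels below 1 and at least 10 CPM. Sets were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. The named identifiers are the 2 with the largest rise and the 2 with the largest fall in DM against GM, by the rule fixed earlier without its requirement of a symbol: adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. That rule was passed by 7996 identifiers.

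Replicates with the same letter deviated together from their group means in 3 of the 15 pairs of groups, with all correlations above 0.1. Across genes these were 0.131, 0.184 and 0.426 for letters A, B and C between GM and DM, and 0.166, 0.377 and 0.558 between DM and SFB. By the criterion fixed before, the letters were taken to pair the libraries in DM against GM and in SFB against DM. The reported tests did not use this pairing, and they called 10199 and 8065 genes. With the letter as a block and only the compared groups in the fit, 11007 and 9759 genes were called.

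Alternatives were RLE scaling, scaling by totals alone, no or a stricter expression filter, DESeq2 1.42.0, only the compared groups in the fit, the replicate letter as a block, and leaving out each library in turn. After the data were seen, thinning to the smallest library, a block with only the compared groups, and a covariate for the first within-group factor were added. Ranges given over the alternative settings cover all of these except leaving out a library.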

Results

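Poly(A) RNA was sequenced from bovine satellite cells, the progenitor cells of skeletal muscle, before and after 72 h of myogenic differentiation with or without fetal bovine serum (FBS). The series is concerned with a serum-free medium for cultured meat that lets these cells differentiate without the serum withdrawal that usually starts the process. At 0 h the cells came from growth medium with 20% FBS (GM) or from serum-free growth medium (SFGM). After 72 h, cells from GM had been differentiated in medium with 2% FBS (DM). Cells from SFGM had been kept in a serum-free base medium (SFB), in serum-free differentiation medium on a DMEM/F-12 base (SFDM), or in that medium on a DMEM base (here the DMEM group). Each of the 6 groups had 3 replicates. The libraries held 16162525 to 28589018 counts assigned to genes, and the lowest total belonged to SFDM replicate A. Of 27607 gene identifiers, 14637 passed the expression filter and were tested. The identifiers were not paired with gene names here, so genes are described as groups defined by their behaviour, with 4 identifiers as examples.

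The groups separated completely. Every distance between replicates of a group, at most 0.475 root mean square log2 units, was below every distance between libraries of different groups, at least 0.619. The first principal component carried 56.4% of the variance and ordered the groups from GM (mean score -103 ± 0.323, SD, n = 3) and SFGM (-76.2 ± 0.666) through SFB (14.7 ± 3.15) to DMEM (48.9 ± 1.05), SFDM (51.2 ± 0.891) and DM (64.7 ± 2.35). The second component, with 16.4%, placed DM (-66.1 ± 3.25) and GM (-27.3 ± 2.25) below the 4 serum-free groups, which lay between 15.6 and 35.3. The third, with 8.60%, placed DMEM (-44.6 ± 1.07) and SFDM (35.7 ± 1.94) at opposite ends.

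**Figure D1:**
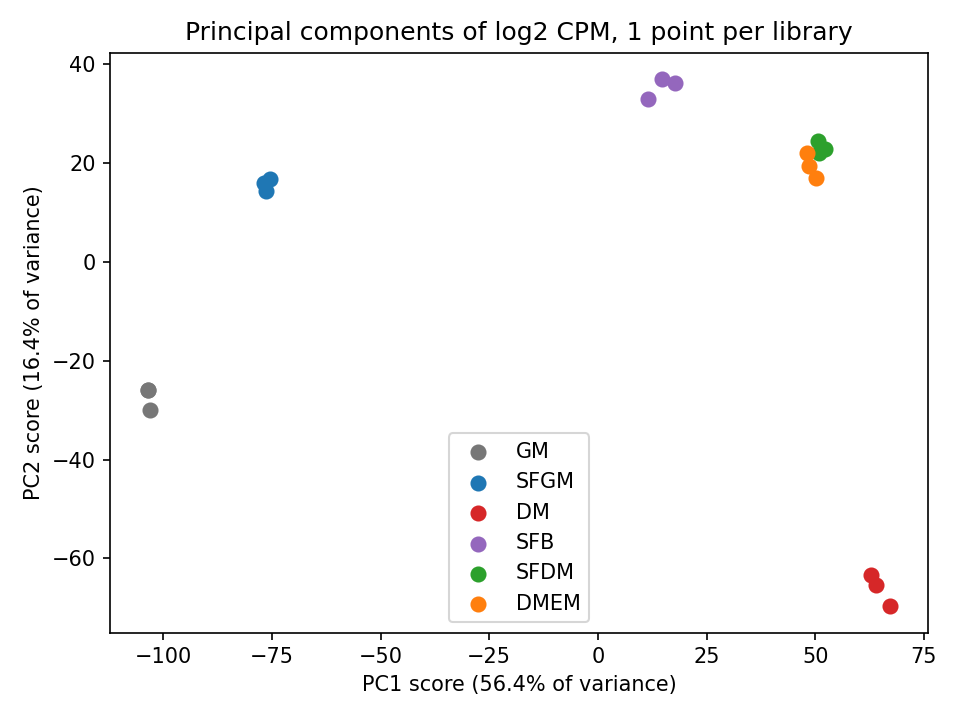
Scores of the 18 libraries on the first (x axis) and second (y axis) principal components of log2 CPM (counts scaled to a common library total), with the percent of variance on each axis; each point is a library, coloured by group. The 0 h groups lie at the left, SFB lies between them and the other 72 h groups, and DM lies below the serum-free groups.

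Serum-based differentiation changed most of the genes tested. Between GM and DM, 4999 genes rose and 5200 fell, and 2653 of the rises and 2167 of the falls were at least 2-fold. The 2653 genes, called serum-induced here, took up 6.54% ± 0.0399 of the counts in GM and 33.6% ± 0.810 in DM (SD, n = 3). The 2167 serum-repressed genes went from 23.5% ± 0.0968 to 6.65% ± 0.0289. Both names refer to serum-based differentiation and not to an effect of serum itself. FBS fell from 20% in GM to 2% in DM, and this cannot be separated from the 72 h of differentiation. By level, 101 identifiers were switched on, from a mean below 1 CPM in GM to at least 10 CPM in DM, and 20 were switched off by the same limits. The tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The sets were defined on these DM and GM libraries, so their values in this comparison are descriptive. Rises made up 49.0% of the calls, 51.2% with RLE scaling and 42.5% with scaling by totals alone, and one of these scalings turned the balance of rises and falls in 11 of the 12 comparisons.

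Among the largest changes, ENSBTAG00000013492 had no count in any GM library and 74.5 ± 9.08 CPM in DM, at least 2122-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 3.6e-14). ENSBTAG00000008763 also went from 0 counts to 27.1 ± 1.87 CPM, at least 772-fold (edgeR adjusted p = 3e-13). ENSBTAG00000038361 fell from 10.7 ± 0.260 CPM in GM to 0 counts in DM, at least 245-fold lower (edgeR adjusted p = 3.8e-12). ENSBTAG00000033748 fell from 8.80 ± 0.798 CPM to 0 counts, at least 202-fold (edgeR adjusted p = 1.06e-10). The rule that chose the 4 identifiers required all 3 DM libraries to lie on the same side of all 3 GM libraries.

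**Figure D2:**
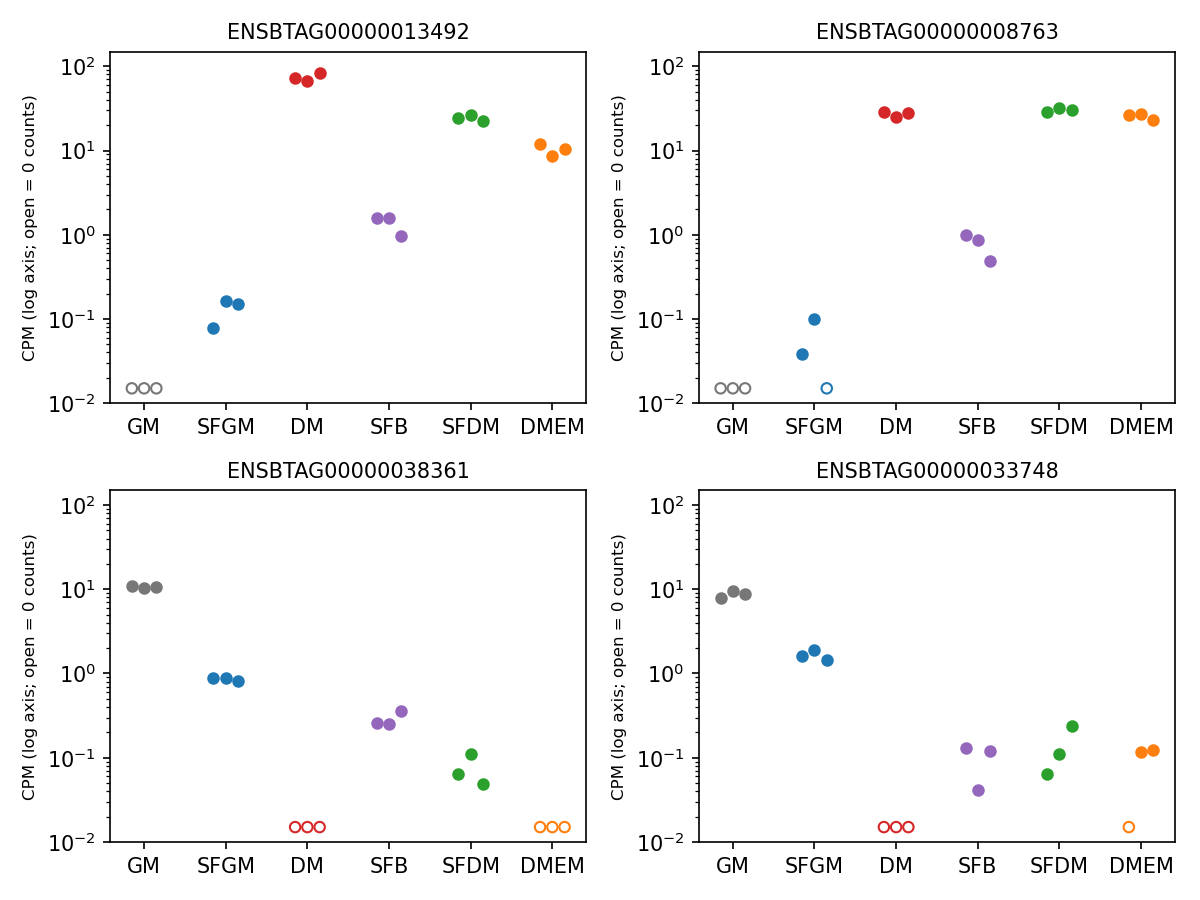
CPM (log y axis) of 4 identifiers in each library, by medium (x axis); filled points are measured values and open points at the bottom are libraries with 0 counts. The upper pair rose from 0 counts in GM to means of 74.5 and 27.1 CPM in DM, and the lower pair fell from 10.7 and 8.80 CPM to 0 counts.

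In all 3 serum-free media the serum-induced genes were up and the serum-repressed genes down at 72 h, compared with SFGM at 0 h. No SFGM libraries were made at 72 h, so the media cannot be separated from the time in culture. Of the 2653 serum-induced genes, 1723 rose in SFB, 1941 in SFDM and 2050 in DMEM, while 161, 149 and 89 fell. The median log2 fold changes of the set were 0.91 in SFB, 1.20 in SFDM and 1.18 in DMEM, against 1.96 in DM. Of the 2167 serum-repressed genes, 1513 fell in SFB, 1697 in SFDM and 1717 in DMEM, with medians of -0.71, -0.97 and -1.04. In all 3 media together 1481 serum-induced genes rose, and 336 rose in none of them. These 3 comparisons share the SFGM libraries and are not independent. The contrast that defined the sets did not include the SFGM and serum-free 72 h libraries. They did enter the expression filter, the scaling and the shared estimate of the spread. With limma's camera at a preset correlation, the adjusted p of the serum-induced set was 6.9e-34 in SFB, 6.08e-47 in SFDM and 7.28e-44 in DMEM. Every one of these 6 calls held with an estimated correlation, where the largest adjusted p was 1.86e-06.

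Counted over all genes tested, 8530 changed in SFB, 8987 in SFDM and 9252 in DMEM against SFGM. In SFB 4171 rose and 4359 fell, in SFDM 4094 rose and 4893 fell, and in DMEM 4683 rose and 4569 fell. The genes that rose in all 3 media numbered 2614, of which 2152 also rose in DM and 123 fell there. The genes that fell in all 3 numbered 2891, of which 2435 also fell in DM. Agreement over the 3 media is not independent, because all were compared with the same SFGM libraries. The edgeR calls made up 48.9% rises in SFB and 45.6% in SFDM, with 50.3% and 50.9% after RLE scaling, and 38.3% and 35.4% when libraries were scaled by their totals alone. That scaling shifted the median of all genes by up to 0.141 log2 units.

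**Figure D3:**
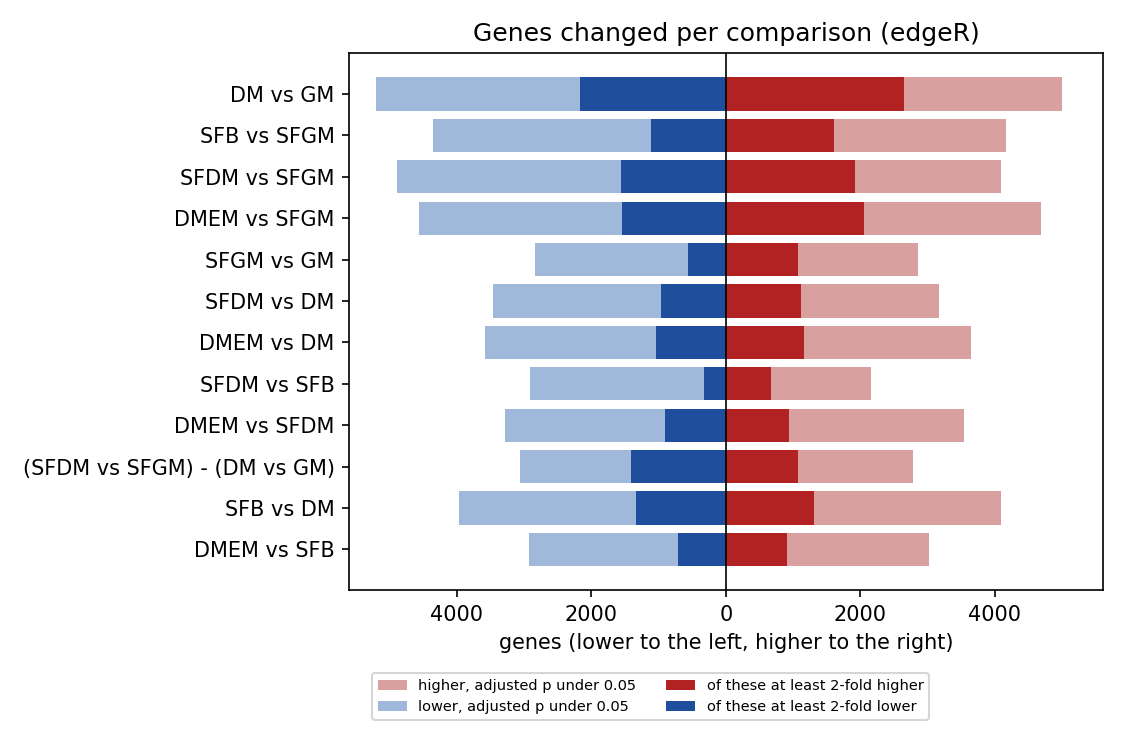
Number of genes (x axis) called higher (right) and lower (left) in each comparison (y axis), with pale bars for all calls at an adjusted p under 0.05 and dark bars for calls of at least 2-fold. DM against GM had the most calls, 10199, and SFDM against SFB the fewest, 5062.

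The response to SFDM and the response to DM involved overlapping genes in matching directions. Of the genes called in both, 6620 moved the same way, where 3137 would be shared by independent lists, and 712 moved in opposite directions, against 3126. Across genes the log2 fold changes correlated with Pearson's r = 0.730 and Spearman's rho = 0.694. For DMEM the numbers were 6804 the same way and 683 opposite (r = 0.747), and for SFB 5879 and 836 (r = 0.634). None of these pairs shared a library, and genes are not independent replicates.

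**Figure D4:**
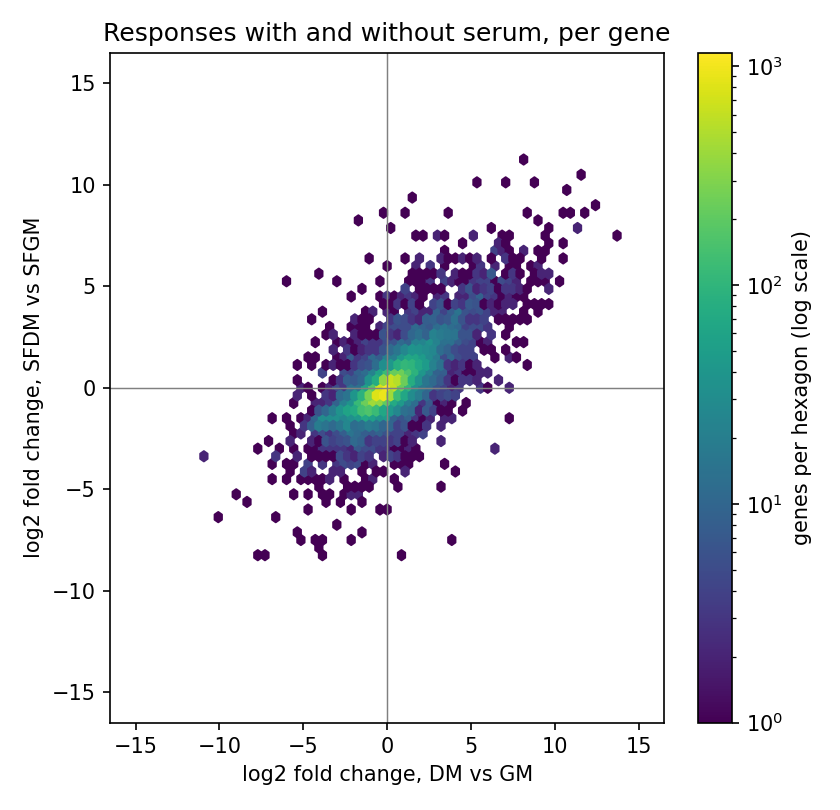
Log2 fold change of each of the 14637 genes in DM against GM (x axis) and in SFDM against SFGM (y axis), with colour giving the number of genes per hexagon on a log scale. Most genes lie in the quadrants where both responses have the same sign (Pearson's r = 0.730 across genes).

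Genes switched on by DM were reached to different degrees without serum. Of the 101 identifiers, 70 had a mean of at least 10 CPM in SFDM, 54 in DMEM, 23 in SFB and 0 in SFGM. Their median level was 25.1 CPM in DM, 18.2 in SFDM, 10.4 in DMEM and 4.67 in SFB. The identifiers were chosen for at least 10 CPM in these DM libraries, which favours a higher level in DM. ENSBTAG00000008763 stood at 30.2 ± 1.74 CPM in SFDM and 25.5 ± 2.20 in DMEM, and ENSBTAG00000013492 at 24.2 ± 2.04 and 10.4 ± 1.67. In SFB they stood at 0.786 ± 0.271 and 1.37 ± 0.353 (SD, n = 3). By the same limits set against SFGM, 60 identifiers were switched on in SFDM, 47 in DMEM and 14 in SFB.

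Before differentiation, SFGM cells already differed from GM cells, partly along the direction of serum-based differentiation. On the second principal component they lay further from DM than GM did. Between GM and SFGM 5701 genes changed, 2863 of them higher in SFGM and 2838 lower. Of the serum-induced genes 1148 were higher in SFGM and 177 lower, with a median log2 difference of 0.48. Of the serum-repressed genes 1025 were lower and 261 higher, with a median of -0.34. Serum-induced genes took up 8.66% ± 0.0287 of the counts in SFGM against 6.54% ± 0.0399 in GM. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. ENSBTAG00000038361 was 12.3-fold lower in SFGM, at 0.869 ± 0.0416 CPM, and ENSBTAG00000033748 5.31-fold lower, at 1.66 ± 0.238 CPM (edgeR adjusted p = 5.56e-10 and 4.23e-07). This comparison and the one that defined the sets share the GM libraries. For genes at least 2-fold higher in DM than GM on mean log2 CPM, chosen without a p-value, the median was 0.43. In 100 simulations of unchanged SFGM libraries, with noise independent between genes, it was at most 0.02. The covariance of the 2 sets of fold changes across genes was 0.397 against a simulated mean of 0.0200. Their Pearson's r was 0.376 against a simulated mean of 0.0670. Over the alternative settings 5233 to 8846 genes were called.

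Most serum-induced and serum-repressed genes that responded differently moved less far in the direction of the serum-based response in SFDM, or against it. The test of the difference between the responses called 5841 genes, and 5415 to 8865 over the alternative settings. Of the serum-induced genes 1362 had a lower log2 fold change in SFDM than in DM, 149 of which fell in SFDM against SFGM, and 120 had a higher one, with a median difference of -0.84. Of the serum-repressed genes 1233 had a higher log2 fold change in SFDM than in DM, 103 of which rose in SFDM against SFGM, and 88 had a lower one, with a median difference of 0.78. For genes chosen as at least 2-fold higher or lower in DM on mean log2 CPM alone, the median differences were -0.81 and 0.76. Unchanged libraries simulated with noise independent between genes gave mean medians of -0.03 and 0.03. The size depended on how genes were chosen. For the 1919 genes that rose at least 2-fold in SFDM against SFGM, the median difference was -0.11, and for 2221 genes whose mean response over both was at least 2-fold it was -0.57.

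At 72 h, 6635 genes differed between SFDM and DM and 7233 between DMEM and DM, with ranges of 3780 to 9444 and 3638 to 9855 over the alternative settings. Serum-induced genes were lower than in DM for 1196 genes in SFDM and 1335 in DMEM, and higher for 446 and 437, with medians of -0.38 and -0.46. Serum-repressed genes were higher than in DM for 1086 and 862 genes, with medians of 0.44 and 0.26. For genes chosen as at least 2-fold higher or lower in DM than GM on mean log2 CPM alone, the SFDM medians were -0.37 and 0.42. SFDM libraries simulated as unchanged from DM, with noise independent between genes, gave mean medians of -0.01 and 0.02. DMEM was not simulated. The direction for rising genes depended on how they were chosen. SFDM against DM had a median of -0.16 for genes whose mean response over both was at least 2-fold up. It was 0.10 for genes that rose at least 2-fold in SFDM against SFGM. In shares of the library, serum-induced genes made up 27.4% ± 0.173 in SFDM and 21.1% ± 0.105 in DMEM, below 33.6% ± 0.810 in DM. Serum-repressed genes made up 12.8% ± 0.102 and 13.0% ± 0.279, above 6.65% ± 0.0289 in DM. Each of these 4 differences had an exact two-sided permutation p of 0.1, the smallest possible. ENSBTAG00000013492 was 3.07-fold lower in SFDM than in DM and 7.14-fold lower in DMEM (edgeR adjusted p = 1.67e-07 and 4.62e-10). ENSBTAG00000008763 did not pass the test in either comparison (edgeR adjusted p = 0.380 and 0.627).

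**Figure D5:**
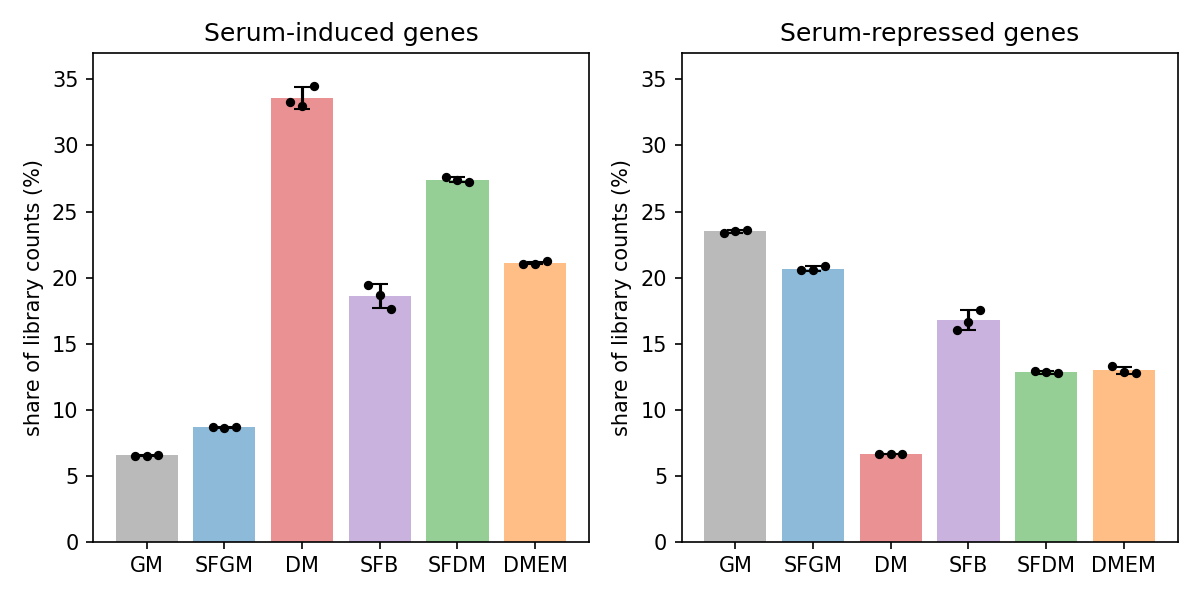
Share of each library's counts (y axis, percent) in the serum-induced genes (left) and serum-repressed genes (right) for the 6 groups (x axis); bars are means of 3 libraries, error bars are SD and points are libraries. Serum-induced genes rise from 6.54% in GM and 8.66% in SFGM to 18.6% in SFB, 21.1% in DMEM, 27.4% in SFDM and 33.6% in DM.

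Both gene sets had moved further in SFDM than in the serum-free base medium. Between SFDM and SFB 2153 genes were higher and 2909 lower in SFDM. Serum-induced genes were higher in SFDM for 1060 and lower for 314, with a median of 0.31 (camera adjusted p = 2.83e-16, or 7.29e-05 with an estimated correlation). Serum-repressed genes were lower for 782 and higher for 95, with a median of -0.27 (camera adjusted p = 1.02e-08, or 0.000325 with an estimated correlation). Of the 101 identifiers switched on by DM, 91 were higher in SFDM than in SFB and 2 lower. ENSBTAG00000013492 was 17.7-fold and ENSBTAG00000008763 38.4-fold higher (edgeR adjusted p = 2.74e-10 and 4.81e-11). Rises made up 42.5% of the edgeR calls, but 52.0% with RLE scaling and 52.9% with only these groups in the fit. The count of 5062 ranged from 1318 to 8506 over the alternative settings, with 3434 for only these groups.

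Comparisons of SFB with DM and with DMEM were added after the data were seen. SFB differed from DM in 8065 genes, with a range of 6392 to 10483 over the alternative settings. Of the serum-induced genes 1657 were lower in SFB and 272 higher, with a median of -0.71, and of the serum-repressed genes 1348 were higher and 102 lower. The sets were defined on the DM libraries, which favours these directions, and SFB was not simulated. DMEM differed from SFB in 5958 genes. There 1017 serum-induced genes were higher in DMEM and 394 lower, and 914 serum-repressed genes were lower and 248 higher. Over the alternative settings 1682 to 9080 genes were called, with 3950 for only these groups.

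Changing the base of the serum-free differentiation medium altered 6816 genes, 3536 higher and 3280 lower in DMEM than in SFDM. The higher genes made up 51.9% of these, 45.9% with RLE scaling and 60.3% with scaling by totals alone. The serum-induced genes went both ways: 914 were lower in DMEM and 679 higher, with a median of -0.14. As a set they did not pass the threshold (camera adjusted p = 0.0548, or 0.177 with an estimated correlation). Their share of the counts was nonetheless lower in every DMEM library than in every SFDM library, at 21.1% against 27.4% on average (exact permutation p = 0.1, the smallest possible). Of the 101 identifiers switched on by DM, 73 were lower in DMEM and 10 higher, with a median of -1.11. ENSBTAG00000013492 was 2.32-fold lower in DMEM (edgeR adjusted p = 5.81e-06), while ENSBTAG00000008763 did not pass the test (log2 difference -0.24, edgeR adjusted p = 0.161, but DESeq2 adjusted p = 0.0118). Serum-repressed genes were lower in DMEM for 700 and higher for 425, with a median of -0.14 (camera adjusted p = 0.00630, or 0.0329 with an estimated correlation). That call was lost when the set was defined without a fold threshold (camera unadjusted p = 0.482 against 0.00577). Their share of the counts was 13.0% ± 0.279 in DMEM and 12.8% ± 0.102 in SFDM (SD, n = 3, exact permutation p = 0.6), but 3 against 3 libraries allow no p below 0.1, so this does not show equal shares.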

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

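The tests of a scaling factor, of the starting level and of genes chosen on scaled responses or on SFDM were chosen after the result was seen. The difference between the serum-free response (SFDM against SFGM) and the serum-based response (DM against GM) passed its own test in 5841 genes. Of the 4 named identifiers, chosen for their change in DM against GM, 3 passed it: ENSBTAG00000013492 (edgeR adjusted p = 0.000325), ENSBTAG00000038361 (edgeR adjusted p = 2.36e-05) and ENSBTAG00000033748 (edgeR adjusted p = 0.000271). ENSBTAG00000008763 did not (edgeR adjusted p = 0.0686). The 3 that passed had 0 counts in GM or DM, so no fold is given for the difference. Of 100 splits that reshuffled the serum label within each time, drawn from 200, 2, the real one included, called at least as many genes. The other, with 6376 genes, kept every group whole and exchanged the names of DM and SFDM. Most splits mix groups that differ, which widens the spread, so this count does not exclude chance.

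The serum-induced genes responded less in SFDM than in DM, with a median difference of -0.84 that depended on how genes were chosen. It was -0.57 for genes chosen on the mean of both responses, -0.52 with each response first divided by its root mean square (1.66 in DM, 1.35 in SFDM), and -0.11 for genes chosen on SFDM against SFGM. The choice may thus set much of the size, and it is argued against only as the whole cause. Whether a higher starting level in SFGM alone accounts for the rest cannot be told apart from a lower end level, because the end level changed direction with the choice of genes. SFDM against DM had a median of -0.38 for the serum-induced genes, -0.16 for genes chosen on both responses and 0.10 for genes chosen on SFDM.

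In the serum-induced and serum-repressed genes and on the first principal component, SFGM libraries were shifted from GM towards DM before differentiation began. On the second component they were shifted away from DM, with means of -27.3 in GM, 15.6 in SFGM and -66.1 in DM. Across genes the fold changes of SFGM against GM and DM against GM correlated at r = 0.376. Noise in the shared GM libraries that is independent between genes is argued against. For genes at least 2-fold higher in DM on mean log2 CPM alone, the highest of 100 simulated medians was 0.0236 against 0.43 observed. Noise that moves many genes together was not simulated, so this test cannot exclude it. A single scaling factor is argued against by the gap of 0.815 between the medians of serum-induced and serum-repressed genes. The shift was not limited to genes that failed to respond in the serum-free media, but it was larger in them. Serum-induced genes that rose in all 3 had a median of 0.36 in SFGM against GM, and those that rose in none 0.79. Serum-repressed genes that fell in all 3 had a median of -0.28, and those that fell in none -0.70. Choosing on rises from SFGM favours genes with a low level there, and choosing on falls favours those with a high level. Partial differentiation in SFGM is a hypothesis that may fit these values, and an effect of the medium on the same genes without differentiation stays open, untested.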

How the results depend on the processing

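The within-group factor, thinning, and the block restricted to compared groups were tried only after the data were seen. Of 198 alternative counts of changed genes, 188 stayed within 1.5 times the reported count. The balance of higher and lower calls turned with RLE or totals scaling in 11 of 12 comparisons. Leaving out single libraries moved no count that far; the widest range was 3912 to 6108 for SFDM against SFB. With the replicate block in the fit of all libraries DM against GM gave 10064 genes and SFDM against SFGM 8817, and the block changed no other call by over 1.5 times. Restricted to the compared groups, the block gave 8581 genes for SFGM against GM, 3780 for SFDM against DM, 3638 for DMEM against DM, 1318 (64.0% rises) for SFDM against SFB and 1682 for DMEM against SFB. In those comparisons not every same-letter correlation passed 0.1 (0.0746, 0.104 and 0.225 between GM and SFGM, and below 0 between the other groups compared here), and 8 of 18 libraries correlated best with their own letter. Without the block that restriction gave 3950 for DMEM against SFB. With the within-group factor as covariate 8846 genes were called for SFGM against GM, 8506 for SFDM against SFB, 8865 for the difference of responses and 9080 for DMEM against SFB. The cause was not tested. Thinning every library to the total of SFDM A kept all 12 counts within 1.5 times. Between DMEM and SFDM the serum-induced set passed camera with scaling by totals (unadjusted p = 0.00770 against 0.0548), with the stricter filter (0.0447) and without DMEM A (0.0362). Tested against no change rather than against other genes, by fry, it had an adjusted p of 0.00438.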

Other observations

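The most abundant genes changed with the medium. The 20 highest genes of each library took up 11.2% ± 0.214 of its counts in GM, 12.2% ± 0.279 in SFGM, 13.9% ± 0.495 in DM, 14.6% ± 0.716 in DMEM, 17.4% ± 0.931 in SFB and 17.7% ± 0.489 in SFDM (SD, n = 3). DM and SFDM shared 15 of their 20 highest genes, as did GM and SFGM and also SFB and SFDM, while GM and DM shared 5. Of the 20 identifiers switched off by DM, 13 were below 1 CPM in DMEM, 10 in SFDM, 9 in SFB and 4 in SFGM. Among the serum-induced genes 32 fell in all 3 serum-free media, and among the serum-repressed genes 53 rose in all 3. The 3 comparisons share the SFGM libraries.

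Libraries of a group varied along a shared axis, noticed in the data and tested only afterwards, which carried 39.2% of the variance within groups and set replicate C apart at the same end in GM, SFGM, DM and SFB, but replicate A at that end in SFDM and DMEM. Unequal depth at counting is argued against, since the axis at equal depth correlated with the axis at full depth at r = 0.9999. Thinning reuses the same reads, so it cannot address what went with depth before counting. Within groups the axis had r = 0.0399 with the log2 library total (exact permutation p = 0.895). The stage of differentiation stays open: within groups the axis had r = -0.0129 with the share of serum-induced genes (exact permutation p = 0.967), but the slope was 2.31 percentage points per unit in DM and -2.08 in SFB. An exchange of the letters A and C in SFDM and DMEM stays open. It raised the mean same-letter correlation from -0.00705 to 0.208, with a lowest value of -0.102 and an SD of 0.177. Of the 45 same-letter pairs 7 stayed below 0, all of letter B, which the exchange does not touch. The prediction for an exchange was that every correlation would be above 0, and it was not met. The lowest value also just passed the limit written against an exchange. It did so by less than the SD, and for that reason the question was left open. Since the exchange was proposed from these correlations, it cannot be told apart from a difference in handling or culture.

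Each comparison of 2 groups has 10 splits of its 6 libraries, too few for a share under 0.05. The real split was the 1 with the most genes in all 11 comparisons. Every other split, those that part the letters included, mixes groups that separated completely, which widens the spread. Low counts in the other splits therefore do not exclude chance. The highest other split called 0 genes against 10199 for DM against GM, 8530, 8987 and 9252 for SFB, SFDM and DMEM against SFGM, 5701 for SFGM against GM, 6635, 7233 and 8065 for SFDM, DMEM and SFB against DM, 5062 for SFDM against SFB and 6816 for DMEM against SFDM. For DMEM against SFB a split that exchanged the C libraries called 2990 against 5958. Where the letters pair the libraries, DM against GM and SFB against DM, the 3 other splits that part every pair also called 0.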
